A study of Homo sapiens with 27 samples.

How the data were processed

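Transcription start sites were profiled by cap analysis of gene expression (CAGE) in NCI-H23 cells (H23), an established non-small cell lung cancer line. The protocol was nAnT-iCAGE, a version without amplification that sequences the capped 5' ends of RNA, made from total RNA per the labels' protocols. Cells received 500 nM JQ1, an inhibitor of the BET bromodomain proteins, or a matched volume of DMSO, the solvent of the drug, and were collected after 3, 6, 12 and 24 h. Untreated cells were collected at 0 h. Each of the 9 groups had 3 libraries, 27 in all. Groups and replicate numbers were taken from the sample titles.

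The deposited values are whole-number counts of CAGE tags per CAGE peak, with 1 table per library. The authors' tables list 201802 peaks, each with a chromosome, start, end, strand, name and count. The submitters' processing notes name BWA, SAMtools and bedtools without versions, and the genome build hg19. The roles and settings of these tools, the source of the peak set and any filter on tags are not given in the sources used here. Each peak carries a strand, but whether tags were counted by strand is likewise not given. Peak starts are counted from 0 in the files and from 1 in the text. A further column of per-library values (1 column) belongs to no sample used here and was not read. The reference annotation at hand was of another build and was not used.

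Peak names pair 97929 peaks with a single gene name, 1980 with more than one, and 101893 with none. Counts of peaks with a single name were summed per name, over 25232 names. Of these names, 5636 are transcript or sequence identifiers and are printed as the files give them. Peaks with more than one name held 3.08% to 4.54% of the tags of a library and stayed out of the gene sums but not out of the peak tests. Ribosomal protein genes and other families have near-identical copies, and tags shared between copies cannot be placed with certainty from these tables.

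Library totals ran from 4034793 to 15450867 tags. A count of 3 tags in a library corresponds to 0.743 CPM (count relative to the library total) in the shallowest library and 0.194 CPM in the deepest. CPM values in the text were computed from the counts with TMM-scaled library sizes and are given as the mean ± SD of 3 libraries. These SDs and any limit from depth cover the spread of these libraries and counting error only.

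Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 13968 genes and, for single peaks, 38411 peaks. Libraries were scaled by TMM, a robust quasi-likelihood fit took all 27 libraries with 1 mean per group, and quasi-likelihood F-tests were run on the contrasts. These were JQ1 against DMSO at each hour, the average of the 4 hours, the 24 h effect minus the 3 h effect, and DMSO at each hour against untreated cells. P-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05, and every adjusted p in the text for a gene or peak comes from these edgeR fits. Unequal change among the CAGE peaks of a gene, called promoter use here, was tested with diffSpliceDGE on the average contrast. The test took 8033 genes with at least 2 tested peaks. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. An exact permutation of 3 libraries against 3 cannot go below p = 0.1.

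Gene lists for pathways, complexes, gene families and markers of other cell types (41 lists) were fixed before the data were examined, and 40 had measured members. They were tested with camera (limma 3.58.1) on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over all lists and the 4 hours. The test was repeated with a correlation estimated per list. Counts of list members that rose or fell come from the edgeR tests over all genes, and counts adjusted over the list alone are given beside them. The share of tags in peaks with no gene name was compared by a two-sided permutation test with 100000 resamples, with labels permuted within each hour.

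The genes named in the text follow a rule fixed before the data were examined. For each JQ1 comparison it takes the 5 risen and 5 fallen genes of largest fitted log2 change with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between JQ1 and DMSO libraries (at all 4 times for the average). It adds MYC, HEXIM1, BRD2, BRD3, FOSL1 and CDKN1A at every hour, and up to 4 members of lowest p for a list. It takes 3 risen and 3 fallen genes for 24 h against 3 h and for DMSO against untreated cells, 3 genes for promoter use, and 2 risen and 2 fallen peaks without a gene name. Of the genes the rule names, 3 are not reported here.

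Each step was tested on simulated counts with 200 changed features drawn from the means and library sizes of these samples. Far more genes were called in the data (8400 of 13968 with JQ1 at 24 h), so the shares below need not hold there. For JQ1 against DMSO at 24 h over 13968 genes, 23.9%, 82.1% and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered, and 0.044% of unchanged genes were called. For the 24 h minus 3 h effect these shares were 6.0%, 35.8% and 89.4%, for the average 82.1%, 92.5% and 100%, and for DMSO at 24 h against untreated cells 35.8%, 62.7% and 97.0%. In 38411 peaks at 24 h, 4.5%, 43.3% and 75.8% were recovered. The promoter use step, run on 8033 genes, found 78% of genes with a 2-fold and 99% with a 4-fold change in 1 peak and called 0.447% of the others. The list step recovered 10 of 10 moved lists and called 0 of 10 unmoved ones, on genes drawn independently. It thus does not test the list calls where genes of a list vary together.

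The alternatives tried were RLE scaling, library sizes alone, other count filters, DESeq2 1.42.0, the compared groups alone, the strongest peak of each gene, peaks with several names, a 2-fold minimum, the replicate number as a block, untreated cells as control, and leaving out each library in turn. Leaving out genes with a peak on the mitochondrial genome, and leaving out DMSO 3 h replicate 2 together with JQ1 6 h replicate 1, were chosen after seeing the data. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom between libraries of a group being 6.01.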

Results

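The series asked how transcription start site activity in a lung cancer line moves with time under BET inhibition. BET proteins bind acetylated histones through bromodomains and recruit the elongation factor P-TEFb, and JQ1 displaces them from chromatin. CAGE tag counts were available for 3 untreated libraries and for 3 JQ1 and 3 DMSO libraries at each of 3, 6, 12 and 24 h. Mean depth per group ran from 5347108 ± 1247533 tags in DMSO at 6 h to 12276968 ± 2135060 tags in JQ1 at 24 h (SD, n = 3). Every library had a peak of MALAT1 or SCARNA2, both noncoding RNAs, as its strongest, and the 10 strongest peaks took 5.03% to 11.8% of a library's tags.

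The first principal component of log2 CPM took 43.0% of the variance and separated all 12 JQ1 libraries from the DMSO and untreated libraries. The second took 17.1% and spread the DMSO libraries by hour. DMSO 3 h replicate 2 lay at -5.53 on the first component, against -30.3 and -27.4 for the other DMSO 3 h libraries and 43.9 for the lowest JQ1 3 h library. Tags on the mitochondrial genome made up 0.335% ± 0.358 of untreated libraries, 1.61% ± 1.63 in DMSO at 3 h, 2.0% ± 0.597 at 6 h, 1.54% ± 0.188 at 12 h and 0.712% ± 0.24 at 24 h (SD, n = 3). In JQ1 libraries the group means lay between 0.505% and 0.786%.

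**Figure D1:**
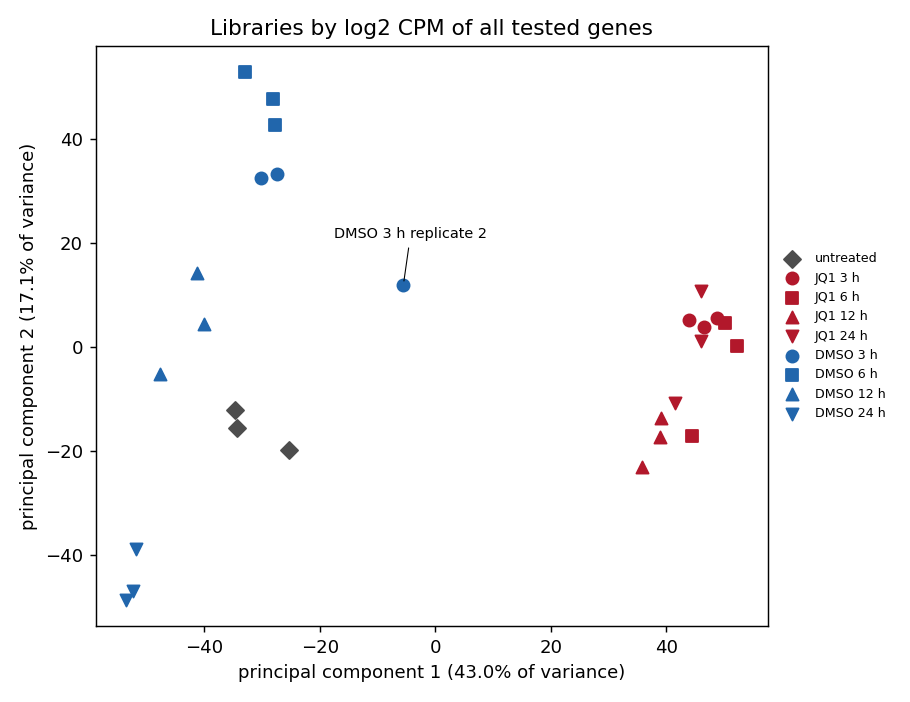
Each point is 1 library, placed by the first principal component of log2 CPM over all tested genes (horizontal, 43.0% of variance) and the second (vertical, 17.1%), with colour for treatment and shape for hour. JQ1 libraries lie at 35.8 or above on the first component, and DMSO 3 h replicate 2 lies at -5.53, apart from the other DMSO libraries.

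HEXIM1 and MYC were higher with JQ1 than with DMSO at all 4 times. HEXIM1, which encodes an inhibitor of P-TEFb (chromosome 17, 43225840 to 43225845, plus strand, hg19, as for all positions here), rose by a log2 change of 2.71 at 3 h (356 ± 33.4 CPM with JQ1 and 54.5 ± 7.62 CPM in DMSO, SD, n = 3), 2.17 at 6 h, 1.77 at 12 h and 1.77 at 24 h. MYC, a transcription factor gene that drives growth (chromosome 8, 128748471 to 128748487, plus strand), rose by 0.87, 1.67, 1.67 and 2.48. Its level in untreated cells was 164 ± 37.9 CPM, and it stood at 357 ± 48.5 CPM with JQ1 and 195 ± 9.8 CPM in DMSO at 3 h and at 440 ± 37.7 CPM with JQ1 and 78.9 ± 6.7 CPM in DMSO at 24 h. Against untreated cells, MYC in JQ1 libraries was higher by 1.12, 1.66, 1.11 and 1.42 at the 4 times (largest edgeR adjusted p = 1.25e-05). CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36646477 to 36646498, plus strand), rose by 1.0, 0.67, 0.68 and 0.59, the last not passing with library sizes alone (0.20).

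Among genes of the drug's targets, BRD3 (chromosome 9, 136933113 to 136933129, minus strand) rose at all 4 times, by 0.58, 0.58, 1.11 and 0.70, though at 24 h it did not pass with library sizes alone (0.31). BRD2 (chromosome 6, 32939965 to 32939988, plus strand) rose by 0.44 at 3 h and 0.88 at 6 h, the 3 h rise no longer passing without JQ1 3 h replicate 3 (0.36) or DMSO 3 h replicate 1 (0.40), or with library sizes alone (0.36). It differed by 0.28 at 12 h (adjusted p = 0.133) and 0.24 at 24 h (adjusted p = 0.155), and without JQ1 12 h replicate 2 it passed at 12 h (0.41). These values are of the sum over its peaks. The strongest peak of BRD2 alone, at the position given and with 72.2% of the gene's tags, rose at 12 h (0.55, adjusted p = 0.0252) and 24 h (0.49, adjusted p = 0.0343). FOSL1, an AP-1 subunit (chromosome 11, 65667847 to 65667868, minus strand), passed the test at no time as a sum over peaks. Its log2 changes were -0.31, -0.11, 0.24 and 0.23, with adjusted p of 0.324, 0.733, 0.431 and 0.413. Of its 3 tested peaks, the strongest did not pass at 24 h (-0.01), while the second, with 30.5% of the gene's tags, rose by 0.77 (adjusted p = 0.031) and the third, with 1.2%, by 1.37 (adjusted p = 0.0103).

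**Figure D2:**
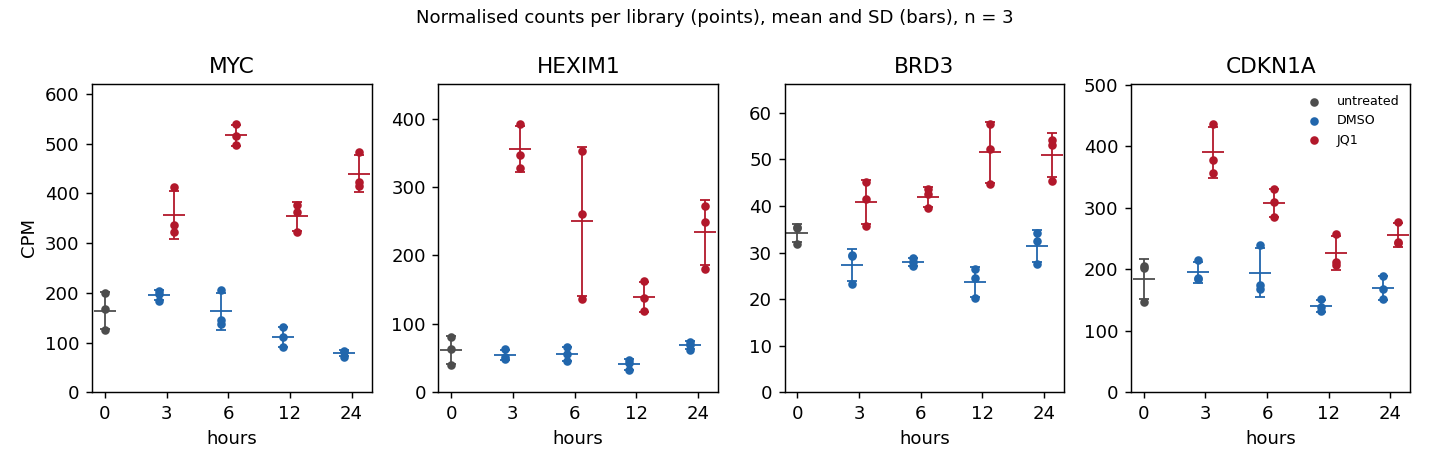
Normalised counts (CPM, vertical, linear from 0) of MYC, HEXIM1, BRD3 and CDKN1A in each library (points) by hours after treatment (horizontal, evenly spaced), with group means and SDs (bars, n = 3) for untreated, DMSO and JQ1 libraries. MYC averaged 440 CPM with JQ1 and 78.9 CPM with DMSO at 24 h, and HEXIM1 356 CPM and 54.5 CPM at 3 h.

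After 3 h of JQ1, PTCHD2, a gene of the patched-domain family (chromosome 1, 11539205 to 11539219, plus strand), rose 28.5-fold, from 3.14 ± 0.40 to 90.2 ± 2.60 CPM (SD, n = 3). FGFR3, a fibroblast growth factor receptor (chromosome 4, 1795013 to 1795028, plus strand), rose by a log2 change of 3.76 (SE 0.25), and NPTX2, a secreted neuronal pentraxin (chromosome 7, 98246589 to 98246604, plus strand), by 3.65 (SE 0.23). DPF3, a subunit of a chromatin remodeller, and NGFR, a neurotrophin receptor, rose by 3.48 and 3.42. PDK4, a kinase that shuts down pyruvate dehydrogenase (chromosome 7, 95225769 to 95225967, minus strand), fell 20.8-fold (1.42 ± 0.25 CPM with JQ1 and 29.9 ± 19.7 CPM in DMSO). The secreted protease gene ADAMTS18 (-4.03), DIO2, which activates thyroid hormone (-3.87), the transcript ENST00000517961 (-3.63) and CYP24A1, which degrades vitamin D (-3.60), also fell.

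Among heat shock genes at 3 h, 5 of 12 measured members rose and 0 fell (6 and 0 adjusted over the list alone). The camera test gave an adjusted p of 0.0318, and an adjusted p = 0.633 with an estimated correlation. HSPH1 and HSPA4L, both chaperone genes, rose by 0.82 and 0.83, the latter only against DMSO, since its log2 difference from untreated cells was -0.04. Among replacement histone genes, which are transcribed outside S phase, 4 of 10 measured members rose and 1 fell (5 and 1 adjusted over the list alone). The linker histone gene H1F0 rose by 2.10 and H2AFJ by 1.41, and camera gave an adjusted p of 0.0491 (0.538 as adjusted p with an estimated correlation).

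In all, 5291 of 13968 genes changed at 3 h, with 2399 risen and 2892 fallen, and 1773 changed at least 2-fold. DMSO 3 h replicate 2 stood apart, and without it 5765 genes changed and 0 lists passed camera (6 at an unadjusted p under 0.05), while replacement histones no longer passed without JQ1 3 h replicate 1 or 3 or DMSO 3 h replicate 1, with 1 list left without either of these JQ1 libraries.

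At 6 h PTCHD2, FGFR3 and NPTX2 again led the rises. PTCHD2 rose by 4.85, FGFR3 by 4.77 and NPTX2 by 4.72 (388 ± 63.5 CPM with JQ1 and 14.5 ± 5.88 CPM in DMSO, SD, n = 3). PCDH19, a cell adhesion protocadherin (4.29), and ARRDC4, an arrestin-domain gene linked to glucose uptake (chromosome 15, 98503923 to 98503964, plus strand, 4.14), rose too. In DMSO these genes stood at 0.44 ± 0.44 and 0.77 ± 0.71 CPM, where 3 tags correspond to 0.46 to 0.74 CPM. The size of these rises is thus uncertain. PDK4 fell by 4.29 on the log2 scale (1.59 ± 0.46 CPM with JQ1 and 32.5 ± 0.71 CPM in DMSO), PAPL, an acid phosphatase gene, by 3.99, and PDE7B, a cyclic AMP phosphodiesterase, by 3.90. SCG2, a secretory granule protein (chromosome 2, 224467069 to 224467085, minus strand), fell by 3.78, and TNFRSF11B, the decoy receptor osteoprotegerin, by 3.68.

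Of the genes of G2/M and mitosis at 6 h, 1 of 32 measured members rose and 19 fell (1 and 19 adjusted over the list alone). The list had a camera adjusted p of 3.38e-04, and an adjusted p = 0.399 with an estimated correlation. PRC1, needed for cytokinesis, changed by -1.23, BIRC5 (survivin) by -1.16 and the mitotic kinase gene PLK1 by -0.85. Of replication histone genes, active in S phase, 2 of 36 measured members rose and 14 fell (2 and 14 adjusted over the list alone), with HIST1H3E at -2.26 and HIST1H2BE at -2.47 (camera adjusted p 0.0165, and adjusted p = 0.832 with an estimated correlation). Of the genes whose names start with RPL or RPS, 5 of 125 measured members rose and 47 fell (5 and 45 adjusted over the list alone). This list also holds pseudogenes and the S6 kinase genes. RPL13P5, a pseudogene by its name, changed by -1.55 and the kinase gene RPS6KA5 by 0.96 (camera adjusted p 0.00137, and adjusted p = 0.832 with an estimated correlation). In DMSO at 6 h against untreated cells, 13 G2/M members rose and 0 fell (14 and 1 adjusted over the list alone), 18 replication histones rose and 0 fell (24 and 0), and 44 RPL and RPS genes rose and 3 fell (52 and 6). These counts were 6 and 5, 9 and 0, and 18 and 8 with library sizes alone.

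Of genes of P-TEFb, the 7SK particle and elongation at 6 h, 11 of 23 measured members rose and 3 fell (11 and 3 adjusted over the list alone). HEXIM1 and the elongation factor gene ELL2 (1.04) led, followed by EAF2 (0.94), a partner of ELL proteins (camera adjusted p 0.0234, and adjusted p = 0.182 with an estimated correlation). Of the zinc finger genes named ZNF, 138 of 424 measured members rose and 61 fell (137 and 59 adjusted over the list alone), with ZNF589 at 1.56 and ZNF618 at -2.40 (camera adjusted p 0.0318, and adjusted p = 0.689 with an estimated correlation). In DMSO at 6 h against untreated cells, 19 ZNF genes rose and 85 fell (18 and 79 adjusted over the list alone, and 3 and 205 with library sizes alone). Across all genes, 6855 changed at 6 h, 3382 risen and 3473 fallen, and 2699 changed at least 2-fold. Without JQ1 6 h replicate 1, which lay apart from the other JQ1 6 h libraries on the second component (-17.2 against 4.56 and 0.10), 3 lists passed camera in place of 5, replication histones and ZNF genes no longer passing, and ZNF genes did not pass without DMSO 6 h replicate 3.

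At 12 h, NGFR (4.15), ARRDC4 (3.93) and DHRS2, a short-chain dehydrogenase gene (chromosome 14, 24105567 to 24105579, plus strand, 3.51, 96.4 ± 6.68 CPM with JQ1 and 8.34 ± 1.8 CPM in DMSO, SD, n = 3), led the rises with NPTX2 (3.45) and PTCHD2 (3.42). SCG2 fell by 5.29 on the log2 scale, from 28.7 ± 2.41 CPM in DMSO to 0.730 ± 0.25 CPM with JQ1. MIR100HG, a host transcript of microRNAs (chromosome 11, 122073794 to 122073812, minus strand, -4.30), CPS1, the first enzyme of the urea cycle (chromosome 2, 211421315 to 211421335, plus strand, -4.25), PAPL (-4.10) and ITPKB, an inositol trisphosphate kinase gene (-4.04), fell as well.

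In the hypoxia and glycolysis list at 12 h, 10 of 22 measured members rose and 0 fell (10 and 0 adjusted over the list alone). The glucose transporter gene SLC2A1 rose by 1.70 and the hexokinase gene HK2 by 1.71 (camera adjusted p 0.00137, and adjusted p = 0.143 with an estimated correlation). In the MYC and MAX network, 6 of 11 measured members rose and 1 fell (6 and 1 adjusted over the list alone). MXD1, which competes with MYC for MAX, rose by 2.19 beside MYC (camera adjusted p 0.0234, and adjusted p = 0.205 with an estimated correlation). Of AP-1 factor genes, 6 of 12 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with ATF3 at 1.37 (camera adjusted p 0.0438, and adjusted p = 0.593 with an estimated correlation). Of immediate early genes, 8 of 20 measured members rose and 2 fell (9 and 3 adjusted over the list alone), with the phosphatase genes DUSP2 at 1.3 and DUSP1 at 1.35 (camera adjusted p 0.0148, and adjusted p = 0.413 with an estimated correlation). Of p53 targets, 11 of 24 measured members rose and 4 fell (11 and 4 adjusted over the list alone), with PLK3 at 1.72 and GADD45A at 1.29, both stress response genes (camera adjusted p 0.0279, and adjusted p = 0.24 with an estimated correlation).

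Of replacement histone genes at 12 h, 7 of 10 measured members rose and 1 fell (8 and 1 adjusted over the list alone), with H1F0 at 2.08 (camera adjusted p 0.0165, and adjusted p = 0.413 with an estimated correlation). In G2/M and mitosis at 12 h, 3 of 32 measured members rose and 14 fell (3 and 15 adjusted over the list alone), with PRC1 at -0.75 and the centromere motor gene CENPE at -0.97 (camera adjusted p 0.0343, and adjusted p = 0.634 with an estimated correlation). Among replication histones, 1 of 36 measured members rose and 12 fell (1 and 11 adjusted over the list alone), with HIST1H3E at -2.45 (camera adjusted p 0.0165, and adjusted p = 0.832 with an estimated correlation). Among RPL and RPS genes, 5 of 125 measured members rose and 52 fell (5 and 55 adjusted over the list alone), with RPL13P5 at -1.34 and RPL32 at -1.32 (camera adjusted p 1.91e-04, and adjusted p = 0.789 with an estimated correlation). Across all genes, 6079 changed at 12 h, 3019 risen and 3060 fallen, and 2156 changed at least 2-fold. AP-1 factors no longer passed camera without JQ1 12 h replicate 3 or DMSO 12 h replicate 3, G2/M and mitosis without JQ1 12 h replicate 1 or DMSO 12 h replicate 3, and replication histones without DMSO 12 h replicate 3.

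After 24 h, HGF, the ligand of the MET receptor (chromosome 7, 81399356 to 81399373, minus strand), fell by 6.06 on the log2 scale (0.15 ± 0.07 CPM with JQ1 and 11.3 ± 2.48 CPM in DMSO, SD, n = 3). The mean with JQ1 lay below 3 tags (0.205 to 0.288 CPM in these libraries), so the size of this fall is uncertain. SCG2 (-5.35), MIR100HG (-5.23), the transcript ENST00000441997 (-4.96) and CPS1 (-4.47) fell too. CTGF, a matrix protein gene induced by YAP and TGF-beta (chromosome 6, 132272505 to 132272519, minus strand), rose 10.8-fold (376 ± 30.3 CPM with JQ1 and 35.0 ± 3.22 CPM in DMSO). The transcripts EF036499 (4.55) and BC009736 (3.91), ARRDC4 (3.56) and PLAGL1, an imprinted zinc finger gene (3.50), were the other largest rises.

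In the hypoxia and glycolysis list at 24 h, 18 of 22 measured members rose and 0 fell (18 and 1 adjusted over the list alone). SLC2A1 rose by 2.76, HK2 by 2.84, ADM (adrenomedullin) by 1.80 and BNIP3, a mitophagy gene, by 2.51. The camera adjusted p was 1.81e-07, and this was the only list to pass with an estimated correlation (adjusted p = 0.00986). Of MYC targets in ribosome biogenesis, 31 of 38 measured members rose and 0 fell (31 and 0 adjusted over the list alone), with the rRNA methyltransferase gene NOP2 at 1.72 and RRP1B at 1.44 (camera adjusted p 2.03e-08, and adjusted p = 0.0817 with an estimated correlation). Of MYC targets in metabolism, 17 of 24 measured members rose and 3 fell (17 and 3 adjusted over the list alone), with HK2 again, the lactate transporter gene SLC16A1 at 2.08 and ODC1, which starts polyamine synthesis, at 2.29 (camera adjusted p 0.00137, and adjusted p = 0.309 with an estimated correlation). Among RPL and RPS genes, 81 of 125 measured members rose and 7 fell (81 and 8 adjusted over the list alone), with RPL13P5 at -1.85, RPS26P47 at 2.26 and RPS2 at 1.35 (camera adjusted p 5.84e-06, and adjusted p = 0.689 with an estimated correlation). Of 15 common control genes, 14 rose and 0 fell, also adjusted over the list alone, with B2M at 2.58 (camera adjusted p 1.99e-04, and adjusted p = 0.413 with an estimated correlation).

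Of heat shock genes at 24 h, 10 of 12 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with the chaperone genes DNAJA1 at 1.60 and HSP90AA1 at 1.85 (camera adjusted p 0.00784, and adjusted p = 0.425 with an estimated correlation). Of NRF2 targets, 12 of 17 measured members rose and 3 fell (12 and 3 adjusted over the list alone), with GCLM at 1.86 and GCLC at 1.45, which encode the enzyme that starts glutathione synthesis (camera adjusted p 0.0165, and adjusted p = 0.24 with an estimated correlation). In the NF-kB list, 13 of 21 measured members rose and 3 fell (13 and 3 adjusted over the list alone). Its leading members were NFKBIA, an inhibitor of NF-kB (2.03), IRF1 (1.0) and TNFAIP3, another inhibitor (-1.18, and -0.08 by its strongest peak alone) (camera adjusted p 0.0341, and adjusted p = 0.413 with an estimated correlation). Of TGF-beta targets, 11 of 17 measured members rose and 2 fell (11 and 2 adjusted over the list alone), with the matrix gene LTBP2 at -2.86 and BAMBI, a decoy receptor gene, at 2.15 (camera adjusted p 0.0234, and adjusted p = 0.24 with an estimated correlation). Of AP-1 factor genes, 6 of 12 measured members rose and 0 fell (6 and 0 adjusted over the list alone), with JUN at 1.40 and JUNB at 1.11 (camera adjusted p 0.0193, and adjusted p = 0.425 with an estimated correlation). Of immediate early genes, 14 of 20 measured members rose and 1 fell (14 and 1 adjusted over the list alone), with CYR61 at 2.71 and KLF10 at 1.26 (camera adjusted p 0.00536, and adjusted p = 0.399 with an estimated correlation).

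Among replacement histones at 24 h, 8 of 10 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with H1F0 at 2.09 and H2AFY2 at -1.81 (camera adjusted p 0.0232, and adjusted p = 0.413 with an estimated correlation). Of G1/S and replication genes, 20 of 40 measured members rose and 4 fell (20 and 4 adjusted over the list alone), with SLBP at 1.26 and the thymidine kinase gene TK1 at 1.22 (camera adjusted p 0.0234, and adjusted p = 0.37 with an estimated correlation). The median of this list was 0.31, and it turned to -0.08 with library sizes alone (8 risen and 10 fallen). Of the ZNF genes, 52 of 424 measured members rose and 166 fell (51 and 162 adjusted over the list alone), with ZNF608 at -2.85 and ZNF618 at -2.78 (camera adjusted p 0.0148, and adjusted p = 0.633 with an estimated correlation). The NF-kB list did not pass camera without DMSO 24 h replicate 2. With library sizes alone, 6 NF-kB members rose and 5 fell at 24 h. The counts were 7 and 2 immediate early genes, 5 and 1 heat shock genes, 8 and 3 NRF2 targets, 8 and 2 TGF-beta targets, and 6 and 0 AP-1 factors. That scaling gave 16 and 1 in hypoxia and glycolysis, 19 and 1 in ribosome biogenesis and 13 and 6 in MYC-target metabolism. It gave 49 and 18 among RPL and RPS genes, 10 and 1 among control genes, 6 and 1 among replacement histones and 14 and 269 among ZNF genes. In all, 8400 of 13968 genes changed at 24 h, 4135 risen and 4265 fallen, and 3726 changed at least 2-fold. With library sizes alone the split was 1993 risen and 6657 fallen, as that scaling moved the median of all genes to -0.408.

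Against untreated cells in place of DMSO, all 40 of these leading changes, 5 risen and 5 fallen at each hour, kept their direction, and 16 were at least 2-fold smaller. PDK4 fell by 2.78 on the log2 scale at 3 h and 2.57 at 6 h, and ENST00000517961 by 2.33 at 3 h. SCG2 fell by 1.72 at 6 h, 3.59 at 12 h and 4.30 at 24 h (8.82 ± 2.23 CPM in untreated cells), CPS1 by 1.86 at 12 h and 2.51 at 24 h, ITPKB by 2.55 at 12 h and ENST00000441997 by 2.79 at 24 h. FGFR3 rose by 3.55 and ARRDC4 by 2.95 at 6 h, NGFR by 3.01 at 12 h, and EF036499 by 2.22 and CTGF by 1.97 at 24 h. BC009736 no longer passed at 24 h (1.10, adjusted p = 0.0589). Of other genes named here, calls were lost in the same way for BRD3 at 3 h (0.26) and 6 h (0.30) and for CDKN1A at 12 h (0.29). They were also lost for PLK1 (-0.14) and RPS6KA5 (0.02) at 6 h and for DNAJA1 (0.44) and KLF10 (0.27) at 24 h. BRD2 passed at 24 h (0.60).

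**Figure D3:**
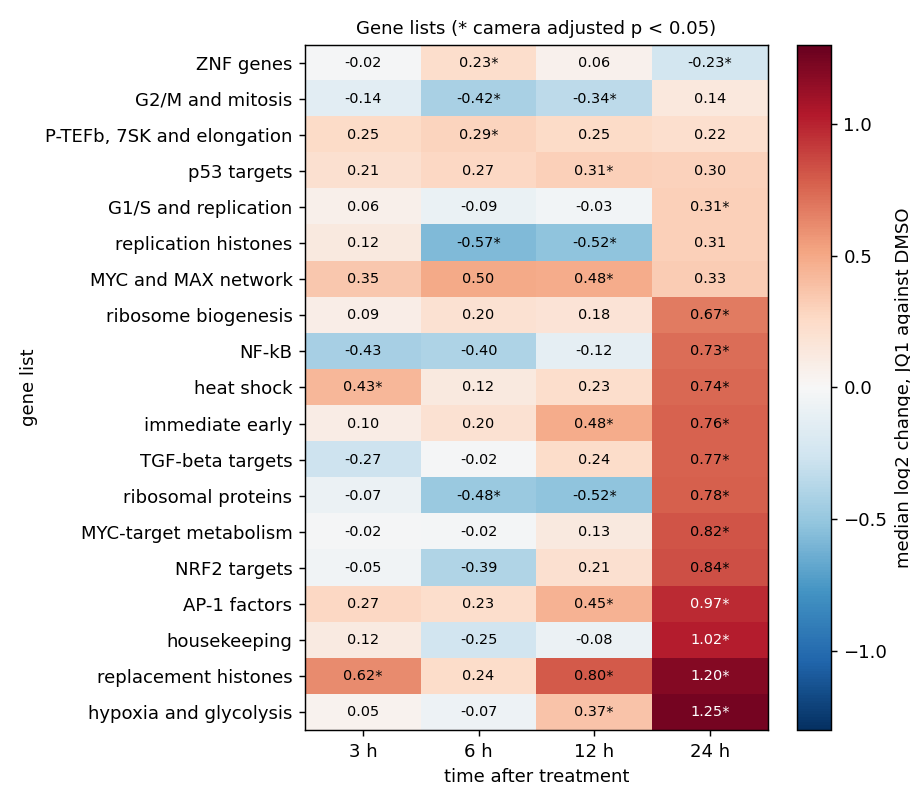
Median log2 change of JQ1 against DMSO (colour and number) over the measured members of each gene list (rows) that passed camera at 1 or more of the 4 times (columns), with an asterisk where the camera adjusted p was under 0.05. Ribosomal protein genes go from -0.48 at 6 h to 0.78 at 24 h, where DMSO against untreated cells gave medians of 0.52 and -0.59, and the hypoxia and glycolysis list reaches 1.25 at 24 h.

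**Figure D4:**
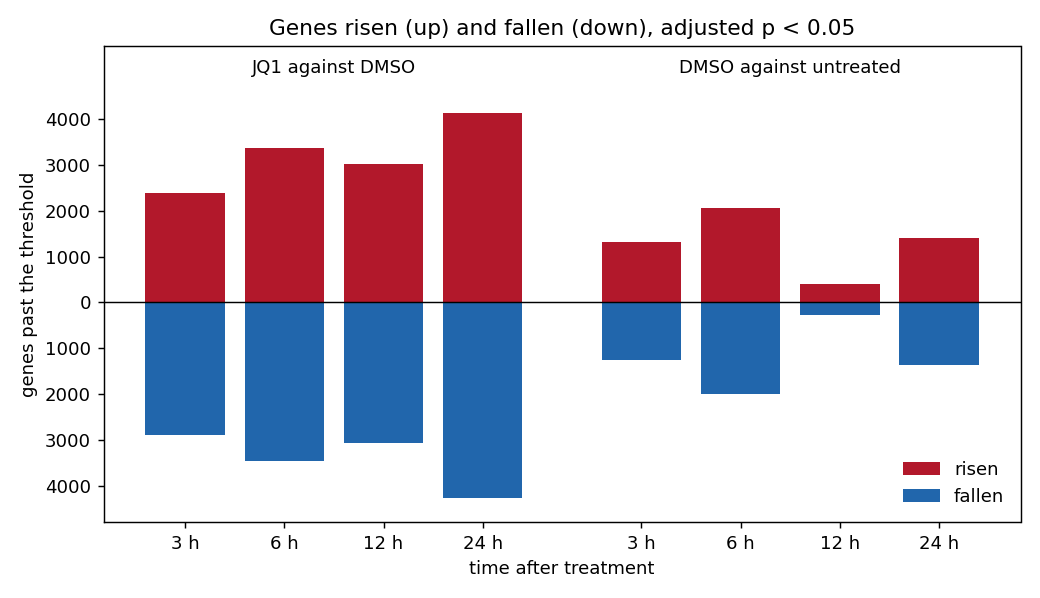
Number of genes risen (above the line) and fallen (below the line) at an adjusted p under 0.05 (vertical) for JQ1 against DMSO and DMSO against untreated cells at each hour (horizontal). JQ1 against DMSO ranges from 5291 genes at 3 h to 8400 at 24 h, and DMSO against untreated cells from 672 at 12 h to 4048 at 6 h.

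Averaged over the 4 times, 9639 of 13968 genes changed, 4749 risen and 4890 fallen, of which 1998 at least 2-fold. The largest average rises were those of PTCHD2 (3.82, SE 0.10), PCDH19 (3.66), NPTX2 (3.63), ARRDC4 (3.49) and FGFR3 (3.47). The largest average falls were those of HGF (-4.51, SE 0.27), PDK4 (-4.17), CPS1 (-3.88), MIR100HG (-3.81) and PDE7B (-3.80). MYC rose by 1.67, HEXIM1 by 2.11, BRD3 by 0.74, BRD2 by 0.46 and CDKN1A by 0.74. FOSL1 (0.01, adjusted p = 0.919) did not pass. The comparisons at the 4 times share no library but come from 1 fit with a shared dispersion. Numbers for independent calls are thus a rough baseline. At all 4 times 926 genes rose (37.2 if the calls were independent) and 1163 fell (48.1 if independent). Opposite calls at 6 h and 24 h were made for 984 genes (2061 if independent) and at 3 h and 6 h for 23 genes (1297 if independent). Leaving out DMSO 3 h replicate 2 and JQ1 6 h replicate 1 together gave 9894 changed genes.

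The JQ1 effect at 24 h differed from that at 3 h for 4430 genes, with 2317 higher and 2113 lower at 24 h, and 2430 by at least 2-fold. The effect on MYC was higher by 1.61 (SE 0.24, adjusted p = 2.23e-05). MYC stood at 195 CPM at 3 h and 78.9 CPM at 24 h in DMSO, and at 357 and 440 CPM with JQ1. Against untreated cells, MYC in JQ1 libraries was higher by 1.12 at 3 h and 1.42 at 24 h. The effect on HEXIM1 changed by -0.94 (adjusted p = 0.0446). The difference for HEXIM1 no longer passed without any 1 of 10 of the 12 libraries (all but DMSO 3 h replicate 2 and DMSO 24 h replicate 2). BRD2 (-0.19, adjusted p = 0.5), BRD3 (0.12, adjusted p = 0.661), FOSL1 (0.54, adjusted p = 0.223) and CDKN1A (-0.41, adjusted p = 0.139) did not pass. AK7, an adenylate kinase gene (chromosome 14, 96858455 to 96858492, plus strand, -3.48), PGF, placental growth factor (chromosome 14, 75422293 to 75422308, minus strand, -3.46), and DMGDH, a choline breakdown enzyme gene (chromosome 5, 78531773 to 78531853, minus strand, -3.28), had the largest negative differences. The largest positive ones were Y17172 (4.28), uc011mfi.1 (3.76) and BC023992 (3.71), whose strongest peaks lie on the mitochondrial genome, where DMSO 3 h libraries held 0.426% to 3.47% of their tags. By list, 17 of 22 hypoxia and glycolysis genes had a higher effect at 24 h and 2 a lower one (17 and 2 adjusted over the list alone). The same held for 27 and 0 of 38 ribosome biogenesis genes (30 and 0), 58 and 2 of 125 RPL and RPS genes (69 and 2), and 14 and 2 of 21 NF-kB genes (15 and 2). With library sizes alone, 1001 genes were higher and 3791 lower, with a median over all genes of -0.306, and CDKN1A passed (-0.73). The list counts were then 15 and 2 in hypoxia and glycolysis, 12 and 0 in ribosome biogenesis, 32 and 7 among RPL and RPS genes, and 9 and 2 in NF-kB.

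DMSO itself was compared with untreated cells, as the background of vehicle and time in culture. CCL20, a chemokine gene (chromosome 2, 228678551 to 228678570, plus strand), was 5.66-fold lower in DMSO at 24 h (123 ± 24.2 CPM with DMSO and 696 ± 97.9 CPM in untreated cells, SD, n = 3), and MYC was lower by 1.06 on the log2 scale. INSIG1, a regulator of sterol synthesis, was higher at 24 h by 2.57, KIAA1328 by 2.86 and LOC728147 by 2.72. The transcripts ENST00000444919 (-2.50) and ENST00000554777 (-2.41) were lower at 24 h. For the lists that passed camera at 24 h with JQ1, counts in DMSO at 24 h against untreated cells were as follows. In hypoxia and glycolysis 1 member rose and 13 fell of 22 (1 and 13 adjusted over the list alone), in ribosome biogenesis 0 rose and 18 fell of 38 (0 and 26), and among RPL and RPS genes 6 rose and 49 fell of 125 (9 and 65). In MYC-target metabolism 0 rose and 11 fell of 24 (0 and 12), and among control genes 1 rose and 8 fell of 15 (1 and 9). In the NF-kB list 1 rose and 10 fell of 21 (1 and 10), and among TGF-beta targets 0 and 10 of 17 (0 and 11). Among immediate early genes 2 rose and 6 fell of 20 (3 and 8), and among heat shock genes 0 and 3 of 12 (0 and 8). Among NRF2 targets 2 rose and 4 fell of 17 (2 and 4), and among AP-1 factors 1 and 1 of 12 (2 and 5). Among G1/S genes 2 rose and 8 fell of 40 (2 and 9), among replacement histones 1 and 1 of 10 (1 and 2), and among ZNF genes 56 and 5 of 424 (42 and 1). Scaled by library sizes alone, 130 ZNF genes rose and 0 fell, and counts were 0 and 11 in ribosome biogenesis, 9 and 38 among RPL and RPS genes, and 5 and 5 among immediate early genes. They were 3 and 2 among NRF2 targets and 4 and 5 among G1/S genes. No camera test was run on these comparisons.

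At the earlier hours, the transcript BC020337 (chromosome 11, 65267145 to 65267219, minus strand) was higher in DMSO than in untreated cells by 5.28 at 3 h, 5.84 at 6 h and 4.30 at 12 h, with 69.5 ± 69.1 CPM with DMSO and 1.72 ± 1.82 CPM in untreated cells at 3 h. MIR21, the precursor of a microRNA (chromosome 17, 57918464 to 57918513, plus strand), was higher by 4.06 at 3 h and 3.49 at 12 h. MTND4P12, by its name a nuclear copy of a mitochondrial gene, was higher by 4.05 at 3 h and 5.0 at 6 h, BC015134 by 4.72 at 6 h, and uc004cov.3, on the mitochondrial genome, by 3.11 at 12 h, alongside the higher mitochondrial share of the DMSO libraries. MTND4P12 at 3 h no longer passed without untreated replicate 1 or 2 or DMSO 3 h replicate 1 (2.14). At 12 h, leaving out single libraries ended the calls of BC020337 (untreated replicates 1 and 2, DMSO 12 h replicates 1 and 3), MIR21 (untreated replicates 1 and 2), LOX (untreated replicate 1) and uc004cov.3 (5 of the 6 libraries). Falls were led at 3 h by AKAP3, a kinase anchor gene (-1.71), ENST00000547799 (-1.64) and ENST00000446022 (-1.62), and at 6 h by AB593186 (-2.25), MEGF6 (-2.09) and ENST00000547799 (-1.72). At 12 h they were led by the collagen crosslinking enzyme gene LOX (-1.43), BAMBI (-1.28) and the homeobox gene HOXC13 (-1.23).

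The number of genes changed between DMSO and untreated cells was 2588 at 3 h (1321 higher, 1267 lower), 4048 at 6 h (2052 and 1996), 672 at 12 h (395 and 277) and 2788 at 24 h (1413 and 1375). With library sizes alone these splits were uneven, with most genes lower at 3, 6 and 12 h and most higher at 24 h. These counts depended on single libraries. Untreated replicate 3 lay apart from the other untreated libraries on the fourth principal component (37.19 against -29.66 and -27.84). Without it the counts were 3556, 3649, 1424 and 3245 at the 4 times. At 3 h the count was 1358 without untreated replicate 1 and 1688 without replicate 2, and at 6 h it was 2572 without DMSO 6 h replicate 1. At 12 h it was 182, 254 and 1424 without untreated replicates 1, 2 and 3, and 251 and 166 without DMSO 12 h replicates 1 and 3. At 24 h it was 1738 without untreated replicate 2 and 1320 without DMSO 24 h replicate 1. With the 6 compared libraries alone, edgeR called 0 genes at 3 h (2719 of 13242 at an unadjusted p under 0.05, and 2849 by DESeq2 on all libraries), 1913 at 6 h, 79 at 12 h and 1598 at 24 h.

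At the level of single CAGE peaks, JQ1 against DMSO changed 11900 of 38411 peaks at 3 h (5674 risen, 6226 fallen), 15113 at 6 h (7862 and 7251), 14138 at 12 h (7150 and 6988) and 20436 at 24 h (9576 and 10860). With library sizes alone far more peaks fell than rose at 3 h and 24 h. CAGE peaks of one gene often changed unequally. Peaks can lie close together, as those of PREPL below, so changed promoter use here can be a shift within 1 promoter. Over the average of the 4 times, 5661 of 8033 genes (70.5%) showed changed promoter use, and 1694 of them had at least 1 peak risen and 1 fallen. In GNAS, which encodes a G protein alpha subunit, 4 peaks rose and 14 fell of 21. The peaks on chromosome 20 at 57464224 to 57464241 and 57464201 to 57464214 rose by 1.22 (SE 0.08, 140 ± 25.1 to 328 ± 61.1 CPM, SD, n = 12) and 2.10, and that at 57466436 to 57466456 fell by 1.79 on the log2 scale. In BRD2, 4 peaks rose and 8 fell of 13. The strongest, on chromosome 6 at 32939965 to 32939988, rose by 0.90 (SE 0.10, 160 ± 36.3 to 298 ± 67.4 CPM), and an upstream peak at 32936354 to 32936398 fell by 0.38 on the log2 scale. In PREPL, a serine hydrolase gene, the peak on chromosome 2 at 44588625 to 44588640 rose by 1.64 (54.5 ± 7.88 to 169 ± 15.1 CPM), while 3 of the 6 peaks fell, among them that at 44588710 to 44588720, by 1.45 on the log2 scale. Adjusted p-values for changed promoter use were 3.20e-115 for GNAS, 2.21e-59 for BRD2 and 3.70e-59 for PREPL by diffSpliceDGE in edgeR.

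**Figure D5:**
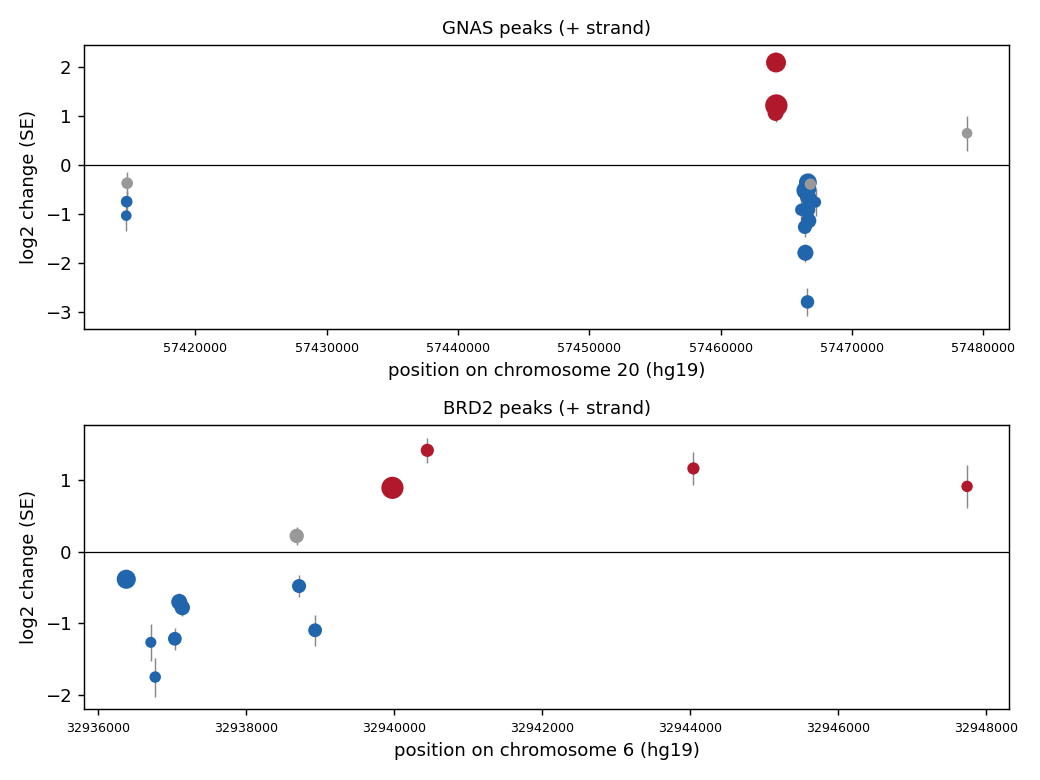
Log2 change of JQ1 against DMSO averaged over 4 times (vertical, bars are SE) for each tested CAGE peak of GNAS and BRD2 by position on hg19 (horizontal), with point size rising with the higher mean CPM, red for risen, blue for fallen and grey for peaks that did not pass. In GNAS the peak at 57464224 rises by 1.22 while 14 peaks fall, and in BRD2 the peak at 32939965 rises by 0.90 while the peak at 32936354 changes by -0.38.

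Of 6142 tested peaks without a gene name, 693 rose and 909 fell at 3 h and 1120 and 790 at 6 h. The counts were 773 and 1049 at 12 h and 1124 and 2121 at 24 h. Of 32269 tested peaks with a gene name, 4981 rose and 5317 fell at 3 h, 6742 and 6461 at 6 h, 6377 and 5939 at 12 h, and 8452 and 8739 at 24 h. In the average over 4 times, the peak on chromosome 9 at 97021591 to 97021594 (minus strand) rose by 3.49 (1.19 ± 0.97 to 11.3 ± 4.83 CPM, SD, n = 12) and that on chromosome 5 at 34929921 to 34929950 (minus strand) by 3.12. The peak on chromosome 20 at 52214240 to 52214244 (minus strand) fell by 3.36 on the log2 scale (36.4 ± 13.1 to 3.78 ± 1.97 CPM), and that on chromosome 19 at 3035620 to 3035623 (minus strand) by 2.88. All peaks without a gene name held 2.76% of tags in JQ1 libraries and 3.04% in DMSO libraries, a difference of -0.281 percentage points that did not pass a two-sided permutation test (p = 0.0972, 12 libraries each). This test averages the hours, and no test was run by hour. By hour the differences were -0.218 at 3 h, 0.375 at 6 h, -0.0602 at 12 h and -1.22 at 24 h. JQ1 and DMSO libraries did not overlap at 3 h and 24 h, and overlapped at 6 h and 12 h. At 24 h the share was 2.69% ± 0.161 with JQ1 and 3.91% ± 0.289 in DMSO, and untreated libraries held 3.09% ± 0.187 (SD, n = 3). Without JQ1 6 h replicate 1 the difference averaged over the hours was -0.349 and passed (permutation p = 0.0248).

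Few markers of other cell types were measured in these libraries, except for fibroblast genes. Of 17 immune marker genes in the files 2 were measured, of 9 endothelial genes 3, of 10 fibroblast genes 6, of 17 alveolar and airway genes 4 and of 11 neuroendocrine genes 4, and no squamous marker was measured. None of these lists passed camera at any time. At 24 h, 4 of the 6 fibroblast markers fell and 0 rose (4 and 0 adjusted over the list alone), with POSTN, a matrix protein gene, at -4.31 and COL3A1, a collagen gene, at -3.09. Of the 4 neuroendocrine markers 2 rose and 0 fell at 3 h, and 2 rose and 1 fell at 24 h, also adjusted over the list alone. Their median log2 changes were 0.915, -0.176, -0.386 and 0.231 at the 4 times. The adhesion molecule gene NCAM1 of this list rose by 2.59 at 3 h and 3.54 at 24 h.

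Some lists moved in both directions and did not pass camera. Among receptor kinases and receptors at 24 h, 6 members rose and 6 fell of 17 (6 and 6 adjusted over the list alone). KIT rose by 1.95, FGFR1 by 1.69 and FGFR3 by 2.13, while the interleukin 7 receptor gene IL7R changed by -3.61. Of 25 genes of histone acetylation at 24 h, 13 rose and 5 fell (13 and 5 adjusted over the list alone). HDAC9, a histone deacetylase gene of this list, fell at each time, by 2.32, 2.20, 2.36 and 2.56 on the log2 scale, and SIRT7, a deacetylase of the nucleolus, rose by 2.83 at 24 h. Of 27 apoptosis regulators at 24 h, 6 rose and 9 fell (6 and 9 adjusted over the list alone), with the initiator caspase gene CASP8 at -1.74 and the death receptor gene TNFRSF10B at 1.3. At 3 h the proapoptotic gene BCL2L11 rose by 1.70 and BIRC3, an apoptosis inhibitor, fell by 1.95 on the log2 scale. Of 20 interferon response genes at 24 h, 5 rose and 8 fell (5 and 8 adjusted over the list alone), with the exonuclease gene ISG20 at -1.93 and the ubiquitin-like modifier gene ISG15 at 2.01. The risen and fallen members at 24 h with library sizes alone were 5 and 8 among receptors, 4 and 9 in histone acetylation, 4 and 14 among apoptosis regulators and 2 and 11 in the interferon response.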

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

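The tests of MYC against untreated cells, of single MYC peaks, of the 24 h lists against untreated cells and all tests of DMSO 3 h replicate 2 were chosen after the results were seen.

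Genes named at 3 h or 24 h are given here where the JQ1 effect at 24 h differed from the effect at 3 h, as the 24 h effect minus the 3 h effect on the log2 scale (edgeR adjusted p from 4.16e-08 to 0.0446, 6 JQ1 and 6 DMSO libraries). Many of these genes were named for a large change at 1 of the 2 times, which favours a difference between them. The difference was positive for BNIP3 (2.90), SLC2A1 (1.90), HK2 (1.90), ADM (1.34), MYC (1.61), ODC1 (2.10), SLC16A1 (1.11), NOP2 (1.63), RRP1B (1.21), RPS2 (0.81) and RPS26P47 (1.85). It was also positive for HSP90AA1 (1.35), DNAJA1 (1.24), GCLM (1.60), NFKBIA (1.64), IRF1 (1.04), CYR61 (2.07), KLF10 (1.83), CTGF (1.66), BAMBI (0.96), JUN (0.63) and JUNB (0.78). Further positive differences were those of B2M (2.40), SLBP (0.57), ADAMTS18 (2.92), CYP24A1 (1.20), EF036499 (2.77) and BC009736 (2.75). Y17172 (4.28), uc011mfi.1 (3.76) and BC023992 (3.71) have their strongest peak on the mitochondrial genome, and without DMSO 3 h replicate 1 uc011mfi.1 no longer passed (2.70).

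The difference was negative for PTCHD2 (-2.67), FGFR3 (-1.63), NGFR (-1.65) and NPTX2 (-0.93), and for HEXIM1 (-0.94), DPF3 (-1.62), H2AFY2 (-1.24), ZNF608 (-0.85) and ZNF618 (-0.97). It was negative as well for AK7 (-3.48), PGF (-3.46), DMGDH (-3.28), HGF (-3.25), LTBP2 (-1.37), MIR100HG (-2.26), ENST00000441997 (-2.63) and RPL13P5 (-0.74). Among genes of lists that moved both ways, the differences were BIRC3 (2.19), KIT (1.92), ISG15 (1.82), SIRT7 (1.78), TNFRSF10B (1.18), BCL2L11 (-0.75), ISG20 (-1.0) and CASP8 (-1.03).

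MYC was higher with JQ1 than with DMSO at all 4 times. Against untreated cells the lowest of the 4 log2 changes was 1.11, which argues against a fall in DMSO alone, although MYC in DMSO at 24 h was lower than in untreated cells. All 15 tested MYC peaks rose in the average (15 of 15), which argues against a single stray peak. With library sizes alone or equal depth the lowest log2 change was 0.801, which argues against depth or the choice among these scalings. All of them are relative to library totals, so a change in total RNA per cell cannot be seen. A rise of MYC start site activity relative to other genes under JQ1 in these cells may thus be biological. This is a hypothesis found and tested on the same data. CAGE counts do not separate synthesis from stability of the RNA, and that was not tested.

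The lists of glycolysis, ribosome biogenesis and ribosomal protein genes passed camera upward with JQ1 against DMSO at 24 h with the preset correlation (adjusted p = 1.81e-07, 2.03e-08 and 5.84e-06). In camera with an estimated correlation only hypoxia and glycolysis passed (adjusted p = 0.00986), and the other lists did not (adjusted p = 0.0817 and 0.689). In hypoxia and glycolysis 13 of all 22 measured members were called higher with JQ1 at 24 h than in untreated cells (59.1%, against 21.1% of other genes, camera with an estimated correlation, adjusted p = 0.00588 over the 3 lists), which argues against a fall in DMSO alone. A rise with JQ1 cannot be told apart from a fall in DMSO for ribosome biogenesis, with 17 of 38 (44.7% against 21.0%, adjusted p = 0.0704), and for ribosomal protein genes, with 20 of 125 (16.0% against 21.2%, adjusted p = 0.6), as these tests did not pass. The 3 medians went from 1.25, 0.67 and 0.78 to 0.85, 0.28 and 0.38 with library sizes alone (lowest 0.279). With every library thinned they were 1.24, 0.63 and 0.73 (lowest 0.634). In each list more than 2 times as many members rose as fell under both. This argues against depth or the choice among these scalings as the whole of it. All of them are relative to library totals, so a change in total RNA per cell cannot be seen and was not tested. Each of these scalings uses 1 factor per library, so a shift that depends on the level of a gene was not tested either. Of 15 common control genes 14 rose too (median 1.02), so a rise at 24 h was not particular to these 3 lists. DMSO at 24 h was itself below untreated cells for 13, 17 and 45 of the risen members of the 3 lists. These were picked by comparison with the same DMSO libraries, which favours low DMSO values. Over all measured members the 3 medians in DMSO at 24 h against untreated cells were -0.916, -0.394 and -0.588. In JQ1 at 24 h against untreated cells they were 0.684, 0.315 and 0.209, smaller in size in each list. Much of each difference may thus come from ageing of the vehicle cultures, for which the design has no untreated cells at 24 h.

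DMSO 3 h replicate 2 lay between the other DMSO libraries and the JQ1 libraries on the first component. JQ1 RNA mixed into it would give the same fraction from risen and fallen genes, yet 447 risen genes gave 0.226 (0.191 to 0.281) and 402 fallen genes 0.621 (0.538 to 0.671). The 11 genes risen at least 8-fold gave 0.068 (0.013 to 0.104). Ranges are 95% bootstrap intervals over genes, which are not independent samples. Genes were chosen partly by the levels that enter the fraction, which can shift these fractions unequally. An exchange with a JQ1 3 h library would leave a JQ1 library out of place, and the lowest JQ1 3 h value was 43.92. A difference in handling shared with untreated replicate 3 cannot be told apart from other causes. The correlation of their deviations was 0.395, 4th of 324 pairs of libraries, with 0.403 the highest of the others. Both stood highest on the fourth principal component (5.3% of variance), untreated replicate 3 at 37.19 and DMSO 3 h replicate 2 at 32.55. Next was JQ1 6 h replicate 1 at 12.79. No biological explanation was tested.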

How the results depend on the processing

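Across 195 single gene results, 2075 values under other settings kept direction and side of the threshold, 25 no longer passed, 2 newly passed and 1 reversed, and 6 had no value because the gene was not in the table tested. HSPA4L at 3 h was the reversed one, at -0.04 with untreated cells as control, and the cause was not tested. Leaving out 1 library kept 1501 of these values, ended 28 calls and added 1. Leaving out mitochondrial genes, and leaving out DMSO 3 h replicate 2 and JQ1 6 h replicate 1 together, were chosen after seeing the data.

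With a 2-fold minimum, a stricter threshold by construction, genes changed by JQ1 numbered 1773, 2699, 2156 and 3726 at 3, 6, 12 and 24 h, 1998 in the average, 2430 for 24 h against 3 h, and 664, 1022, 178 and 668 for DMSO against untreated cells. Peaks numbered 6659, 9409, 8211 and 13068. With only the 6 compared libraries, and so fewer samples, DMSO against untreated cells gave 0 genes at 3 h by edgeR (2719 at an unadjusted p under 0.05, DESeq2 2849 on all libraries), 1913 at 6 h, 79 at 12 h and 1598 at 24 h. Gene lists passing camera with an estimated correlation were 0, 0, 0 and 1 at the 4 times (2, 3, 4 and 9 at an unadjusted p under 0.05). Without a count filter 4 lists passed at 3 h and 10 at 6 h, and with RLE scaling 1 at 3 h, and the cause was not tested.

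The other settings gave 4168 to 6405, 5608 to 7051, 5055 to 6702 and 5976 to 9483 genes for JQ1 at the 4 times, 9242 to 10028 for the average, 4053 to 5015 for 24 h against 3 h and 5010 to 5861 genes for promoter use. With library sizes alone the split of risen and fallen was 1993 and 6657 at 24 h, 1001 and 3791 for 24 h against 3 h, 597 and 2951, 857 and 4426, 209 and 548, and 2623 and 833 for DMSO against untreated cells, and 3788 and 8631 peaks at 3 h and 5437 and 16146 at 24 h. The median of all genes moved to -0.111 at 3 h, -0.408 at 24 h, -0.101 in the average, -0.306 for 24 h against 3 h, and -0.22, -0.318, -0.131 and 0.177 for DMSO, and that of peaks to -0.224 at 3 h and -0.452 at 24 h.

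Leaving out 1 library at a time gave 4164 to 5765, 5881 to 6425, 4944 to 5745 and 7364 to 7867 genes for JQ1 at the 4 times, 9419 to 9811 in the average and 3488 to 4646 for 24 h against 3 h. It gave 1358 to 3556, 2572 to 3649, 166 to 1424 and 1320 to 3245 for DMSO against untreated cells. Peaks ran from 8921 to 13422, 12241 to 13849, 11159 to 12844 and 17377 to 18892, genes with changed promoter use from 5466 to 5684, lists from 0 to 3, 3 to 6, 6 to 10 and 13 to 14, and the share of peaks with no name from -0.3493 to -0.2387.

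Replicate numbers did not pair the libraries, as 19 of 108 pairs of the same number had a correlation above 0.1 (median 0.006) and 8 of 27 libraries were closest to one of their own number. With the replicate number as a block, 5223, 6817, 6014 and 8338 genes changed at the 4 times, 9596 in the average and 4354 for 24 h against 3 h, 1 list passed at 3 h in place of 2, and the share of peaks with no name had a permutation p of 0.189. Of simulated 1.5-, 2- and 4-fold changes at 24 h, 23.9%, 82.1% and 98.5% were recovered for genes and 4.5%, 43.3% and 75.8% for peaks. The simulation changed 200 features, far fewer than were called in the data, so these shares need not hold there.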

Other observations

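All counts of other splits of the samples here were chosen after the results were seen. Each count below is of splits with a result as large as the real one, the real one included.

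For the average of the 4 times, 1 of 100 splits gave as many genes as the real 9639 (highest other 2652). For promoter use 1 of 100 gave as many as 5661 (highest other 1583). For both this is the lowest share that 100 splits can give, which argues against chance among these libraries. Replicates may be technical, so the splits do not cover chance between cultures. For the 24 h against 3 h effect, 6 of 100 splits gave as many as 4430 genes (highest other 6532). These splits cannot decide whether that difference is chance. Mixing the labels of 1 hour alone keeps the JQ1 difference of the other hour in the contrast. All 5 of the other splits as large left the 24 h labels unmixed, so they kept the 24 h difference between JQ1 and DMSO. Chance is thus neither excluded nor shown for this effect.

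Splits of 3 libraries against 3 number 10, too few for a share under 0.05. For genes changed by JQ1, 1 of 10 splits was as large at 3 h (5291, highest other 85), 1 of 10 at 6 h (6855 and 5), 1 of 10 at 12 h (6079 and 0) and 1 of 10 at 24 h (8400 and 0), by edgeR. For CAGE peaks it was 1 of 10 at 3 h (11900 and 300), 1 at 6 h (15113 and 2), 1 at 12 h (14138 and 0) and 1 at 24 h (20436 and 0). For DMSO against untreated cells it was 1 of 10 at 3 h (2588 and 1902), 1 at 6 h (4048 and 71), 1 at 12 h (672 and 166) and 1 at 24 h (2788 and 209). For gene lists, 9 of 10 splits were as large at 3 h (2 lists, highest other 9), 5 of 10 at 6 h (5 and 8), 1 of 10 at 12 h (9 and 7) and 3 of 10 at 24 h (14 and 14). The median of the other splits was 5, 4, 5 and 8 lists at the 4 times by camera with a preset correlation. Each mixed group of 3 holds JQ1 and DMSO libraries in unequal number, so part of the JQ1 difference stays in these splits. They thus cannot tell whether such lists are false calls.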
